A study of Mus musculus with 8 samples.

How the data were processed

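RNA was measured on 8 one-colour (Cy3) Agilent whole-genome mouse arrays, 1 per sample. The cells were primordial germ cells made in culture from V6.5 mouse embryonic stem cells, which carried DAZL fused to GFP and a V5 tag and were harvested after 12 days of differentiation. DAZL is an RNA-binding protein of germ cells. Per the labels' protocols, RNA immunoprecipitation (IP) was done on native lysates without ultraviolet crosslinking, and RNA was extracted with TRIZOL. The 4 groups, with 2 arrays each, were total input RNA, a mock IP with normal mouse IgG, an IP with an antibody against V5 and an IP with an antibody against GFP. Whether the replicates came from separate cultures is not given in the sources used here, so p-values measure the spread between these arrays, which may be technical in part.

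Per the file headers, the arrays were read with Agilent Feature Extraction 9.1.3.1, and each array's values are linear spot intensities. The processed intensity is background-subtracted and detrended, with a substitute value for spots not above background, per the file headers. The mean spot intensity and the local median background of the same deposited tables were used for an alternative. The authors also deposited a table of the whole series. Per the file headers, its signal values are background-subtracted signals normalized to the median in GeneSifter. Its deposited quality score served only to match the table to spots: all 45018 entries matched 1 spot within a tolerance of 1e-05. The deposited signal divided by the background-subtracted signal over the array median had a median between 0.999 and 1.00 on the 8 arrays. That table was used as an alternative, as log2 of the signal plus 0.1. All columns of per-sample values in it were assigned to a sample.

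The main values were log2 of the processed intensity minus the array's 75th percentile over the probes of genes. Spots of 1 probe were averaged without outlier spots. A probe was kept when it was well above background on both arrays of at least 1 group, which left 28104 of 41174 probes. The kept probe with the highest mean over the 8 arrays stood for its gene, giving 19032 genes. Of 6546 genes with more than 1 kept probe, 1763 had probes of opposite sign in V5 IP against mock IP and 1866 in GFP IP against mock IP. No tested gene was saturated on any array. Gene names came from the RefSeq gene table of GRCm38.p6: 22951 probes were named through their accession, 6659 already had a current symbol, 3096 had a synonym of a single symbol, and 8468 kept the name in the file. The table's coordinates were not used.

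Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 8 arrays with 1 shared estimate of the spread. P-values were adjusted by Benjamini-Hochberg over all genes, with a call at an adjusted p under 0.05. Because the spread is shared, the input arrays also enter the p-values of each IP against mock IP. With all groups, 2776 genes were called higher and 4066 lower in V5 IP against mock IP. With only the groups compared, which leaves fewer arrays, these were 2037 and 382. Log2 fold changes are given with the standard error (SE) of the fit. Where a gene was not well above background on the arrays of the dimmer group, its fold is written "at least". Where it was well above background on some of them, the number of arrays is given. That bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. The number of arrays limits the precision of every value.

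The comparisons, the 20 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Dazl first in every comparison. For each IP against mock IP it took the 12 highest and the 8 lowest log2 fold changes among calls, and for other comparisons the 6 highest and the 6 lowest. Both arrays of 1 group had to lie above both of the other, and clone names and accession-like names were left out. Where a direction had too few calls, the genes with the smallest p were taken. From each list it took the 2 members with the largest and the 2 with the smallest moderated t in each IP against mock IP.

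Lists were tested with camera in limma, with a preset correlation of 0.01 between genes and adjustment over 100 tests (20 lists in 5 comparisons). Of these, 46 passed with the preset correlation and 0 with an estimated correlation, and fry, which does not set a list against other genes, passed 40. Of 646 measured list genes, 19 were in more than 1 list. The median log2 fold change of all genes was -0.44 in V5 IP and in GFP IP against mock IP, -0.11 in both against input and 0.20 in mock IP against input. List shifts are therefore given relative to the median of all genes.

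Replicate 1 of every group lay on slide 1 and replicate 2 on slide 2, which were scanned apart. Each group had the same position on both slides, so position and group cannot be told apart. The deviations of same-numbered arrays from their group means correlated across genes in all 6 pairs of groups, from 0.30 for input with V5 IP to 0.78 for V5 IP with GFP IP. Same-numbered arrays share a slide and a scan. Whether they also share a culture or a preparation is not given in the sources used here, so the origin of the pairing cannot be told. A fit with the replicate number as a block is the same as a fit with the slide as a block. Differences within each slide have no test.

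Alternatives were quantile normalization, the median of probes well above background on all arrays, normexp background correction (offset 50) on the mean and background intensities, no filter on dim probes, a stricter filter, the mean of all kept probes of a gene, the replicate block, only the groups compared, a minimum fold of 2, eBayes with a trend, the authors' deposited table, and leaving out each array in turn. Centring on the median of the tested genes, and leaving out arrays in the list tests, were chosen after seeing the data. With 1 array left in a group, that array was assumed to vary like the other groups. The correlation and overlap of the 2 IPs were set beside 100 simulated data sets in which unchanged IPs shared the mock arrays and all arrays were independent. A further 100, chosen after seeing the data, gave same-numbered arrays the measured correlations. The steps were tested on simulated data for V5 IP against mock IP over 19032 genes, of which 200 were changed: 69 of 100 genes changed 4-fold and 0 of 100 changed 2-fold were called, with 4 false calls. A shift given to 1 simulated list of 73 genes was found in 2 of 2 tests, and 0 of 98 other list tests passed. In these simulated data genes and arrays varied independently. They therefore do not show how often calls are false with correlated genes or same-numbered arrays. The data had 6842 calls in V5 IP against mock IP, far more than the 200 changed genes simulated. The adjustment is then less strict, so the recovered shares do not carry over to the data. Of the 6842 calls 4951 were at least 2-fold, and the others were smaller. Some genes that the rule for named genes took are not reported here.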

Results

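RNA recovered with tagged DAZL from mouse primordial germ cells made in culture was compared with RNA from a mock IP and with total input RNA. DAZL, an RNA-binding protein of germ cells, carried GFP and a V5 tag, so that antibodies against either tag bind the same fusion protein. Each of the 4 groups (input, mock IP, V5 IP and GFP IP) had 2 arrays. Between 61.3% (mock 1) and 70.5% (input 1) of 41174 probes were well above background. The 75th percentile of the processed intensity was 363 on mock 1 and 791 on mock 2, and lay between 665 and 1170 on the other arrays. The first principal component held 57.7% of the variance and set the V5 and GFP arrays apart from the input and mock arrays. The second, with 24.5%, set mock 1 apart.

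Dazl mRNA itself was higher with both antibodies than in mock IP. Its normalized log2 signal was 4.18 ± 0.20 (SD, n = 2) in V5 IP, 4.27 ± 0.52 in GFP IP, 1.55 ± 0.70 in mock IP and 2.88 ± 0.07 in input. Dazl rose 6.19-fold in V5 IP over mock IP (log2 2.63 ± 0.39 SE, adjusted p = 0.00500) and 6.56-fold in GFP IP over mock IP (log2 2.71 ± 0.39, adjusted p = 0.00394). Within slides, Dazl lay 2.98 and 2.27 above mock IP in V5 IP, and 2.84 and 2.59 above it in GFP IP. Dazl also rose over input, 2.46-fold in V5 IP (adjusted p = 0.0419) and 2.61-fold in GFP IP (adjusted p = 0.0298). Both calls over input ended without input 1 or input 2 (adjusted p of up to 0.175 in V5 IP and 0.136 in GFP IP) and with quantile normalization, normexp or no filter on dim probes. The V5 call also ended without V5 1, without V5 2 and with the mean of all probes, and the GFP call without GFP 2. In mock IP against input Dazl lay at -1.33 ± 0.39, which did not pass (adjusted p = 0.0641) but passed with the slide as a block (0.0123). The second Dazl probe moved in the same direction in each comparison. Whether the probes also read the tagged transcript is not given in the sources used here.

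**Figure D1:**
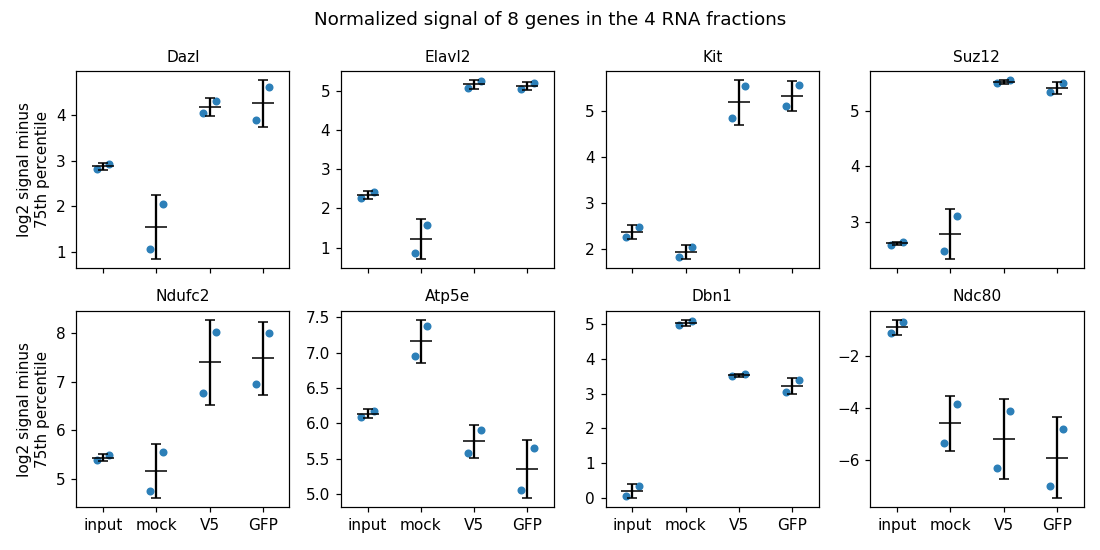
Normalized log2 signal (log2 intensity minus the array's 75th percentile) of 8 genes in input, mock IP, V5 IP and GFP IP. Points are the 2 arrays and bars the mean ± SD; Dazl had means of 1.55 in mock IP and 4.18 in V5 IP, and the vertical axes do not start at 0.

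V5 IP against mock IP asks which RNAs gave more signal, relative to their array, with an antibody against the tag than with normal IgG. Each array was scaled to its own signal. Folds in all comparisons are therefore relative to the other RNA of an array and are not amounts recovered. A gene lower than in mock IP was thus not shown to be recovered in a smaller amount. Elavl2, an RNA-binding protein of the Hu family, rose 15.3-fold (log2 3.94 ± 0.29, adjusted p = 0.00213). Sycp3, a component of the synaptonemal complex of meiotic chromosomes, rose 12.4-fold (log2 3.63 ± 0.60, adjusted p = 0.00775). Nmt2, an N-myristoyltransferase, rose 13.7-fold, Taf7, a subunit of the general transcription factor TFIID, 12.7-fold, and Rnf138, a ubiquitin ligase, 12.0-fold. Dck, deoxycytidine kinase, rose 11.9-fold and Cyp51, an enzyme of cholesterol synthesis, 11.8-fold. Arxes1, the transcription elongation factor gene Tcea1 and the ubiquitin-conjugating enzyme variant gene Ube2v2 rose 11.5-fold, 11.2-fold and 10.8-fold. Foxa1, a forkhead transcription factor of endoderm, and Synpr, a synaptic vesicle protein gene, were not well above background in mock IP and rose at least 4.82-fold and at least 7.60-fold. Among the lowest, the calcium channel subunit gene Cacng3 was at least 5.26-fold lower, Cypt2 at least 3.04-fold, Wfikkn2 at least 2.67-fold and Prrxl1 at least 2.30-fold. Sox8 was lower too, but was well above background on 1 of 2 mock arrays, so no fold is given. Ly6m lay at -2.15 ± 0.31 (adjusted p = 0.00458), the growth factor gene Vegfb at -2.12 ± 0.37 (adjusted p = 0.00921) and Il1f8 at -2.03 ± 0.56 (adjusted p = 0.0316).

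By limma, 2776 of 19032 genes were higher and 4066 lower in V5 IP than in mock IP, and with the slide as a block 3693 were higher and 7311 lower. Within slides, 3561 genes were at least 2-fold higher and 5575 at least 2-fold lower on slide 1, and 2144 and 644 on slide 2. The higher and lower counts were 948 and 10 with normexp, 3054 and 1506 with the authors' deposited table, and 2833 and 1557 with centring on the median of the tested genes. The 2776 and 4066 became 1063 and 55 without V5 1, 1060 and 77 without mock 1, 1788 and 426 without input 1 or without input 2, and 2634 and 2008 without V5 2. All 12 of the highest genes kept their call whichever array was left out, though Foxa1 and Synpr lost it with normexp. Of the 8 lowest, 3 kept theirs: Cypt2, Sox8, Prrxl1, Wfikkn2 and Il1f8 lost it without mock 1, with an adjusted p of up to 0.185 for Wfikkn2 without mock 2. With normexp 7 of the 8 lowest lost it.

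GFP IP against mock IP asks the same question with the other antibody. Nmt2 rose 16.4-fold (log2 4.04 ± 0.31, adjusted p = 0.00176), with 1 of its other probes moving the opposite way. Elavl2 rose 15.0-fold (log2 3.90 ± 0.29, adjusted p = 0.00176), Taf7 13.2-fold, Cyp51 12.7-fold, Dck 12.4-fold, Arxes1 11.6-fold and Tcea1 11.1-fold. Sap30, a subunit of the Sin3 histone deacetylase complex, and Ccnb1ip1, a protein of meiotic crossover formation, each rose 11.2-fold. Synpr rose at least 8.18-fold, Foxa1 at least 4.94-fold and Tmem132cos, an opposite-strand transcript, at least 2.46-fold. The interleukin gene Il1f10 was at least 3.83-fold lower, Cacng3 at least 4.52-fold, Cypt2 at least 2.61-fold, Ccdc78 at least 2.60-fold and the Nogo receptor gene Rtn4r at least 2.30-fold. Cbln3 was lower too, but was well above background on 1 of 2 mock arrays, so no fold is given. Ly6m lay at -2.94 ± 0.31 (adjusted p = 0.00189). Fam71b was also lower (adjusted p = 0.0442), but was well above background on 1 of 2 GFP arrays, so no fold is given.

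By limma, 3102 genes were higher and 5043 lower in GFP IP than in mock IP, and with the slide as a block 3969 were higher and 7645 lower. They were 2540 and 3156 with no filter on dim probes, and 2738 and 2917 with only the groups compared. Within slides, 3676 genes were at least 2-fold higher and 5896 at least 2-fold lower on slide 1, and 2520 and 1526 on slide 2. The higher and lower counts were 1173 and 450 with normexp, 3518 and 2790 with the authors' deposited table, and 3351 and 2873 with centring on the median of the tested genes. The 3102 and 5043 became 1338 and 138 without GFP 1, 1711 and 1042 without mock 1, 2663 and 2602 without GFP 2, and 2511 and 3018 without input 1 or without input 2. Of the 12 highest genes 11 kept their call whichever array was left out: Tmem132cos lost it without mock 1 (adjusted p = 0.0841) or mock 2. Of the 8 lowest 5 did: Il1f10 lost it without mock 2 (adjusted p = 0.150) or GFP 2, Cypt2 without mock 1 (0.0642), and Fam71b when any 1 of 5 arrays was left out (0.254 without mock 1). With normexp Cbln3 changed sign and the other 7 lost their call, as did Synpr, Foxa1 and Tmem132cos.

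**Figure D2:**
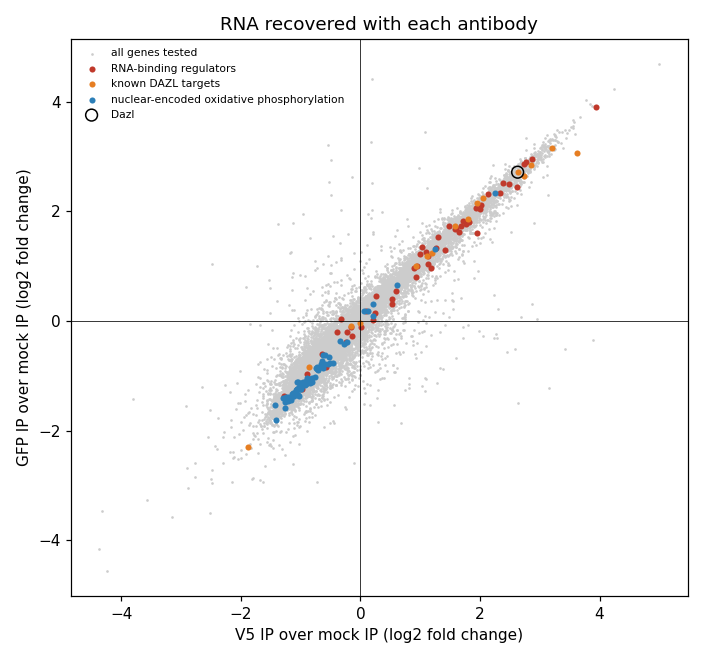
Log2 fold change of 19032 genes in V5 IP over mock IP (horizontal axis) and in GFP IP over mock IP (vertical axis). Each point is a gene, 3 gene lists are coloured and Dazl is circled; the values follow each other across genes with r = 0.963.

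Gene lists were set against all other genes in the same comparisons. Of 64 list members called in V5 IP against mock IP under the naming rule, beyond those among the highest genes, 19 kept their call whichever array was left out. Without V5 1 44 lost it, and without mock 1 44. Of 68 such members in GFP IP, 25 kept their call, and 43 lost it without GFP 1. Every named list member that fell in V5 IP, other than H1f4, lost its call without V5 1, as did Ndufc2, H3c4, H3c14, Isl1, Kmt2a and Pecam1 among those that rose. In GFP IP, Atp5e, H1f4, H1f5 and Bmp4 were the named list members that fell and kept their call without GFP 1, and Kmt2a, Ndufc2, H3c4 and Pecam1 were among those that rose and lost it. Shifts of a list are medians minus the median of all genes, and are given for each slide where a list passed. Counts of members are from the fit without a slide block. With the block, the count in at least 1 direction moved by over 1.5 times in 74 of 100 list tests. Member counts are calls against a fold change of 0, while the median of all genes was -0.44 in each IP against mock IP. Over all 19032 genes, 2776 were higher and 4066 lower in V5 IP, and 3102 and 5043 in GFP IP. With normexp the lower calls over all genes were 10 in V5 IP and 450 in GFP IP.

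mRNAs of RNA-binding regulators were higher in both IPs than in mock IP. Of 52 measured members, 28 rose and 2 fell in V5 IP, and 29 rose and 2 fell in GFP IP. Adjusted over the list alone, 32 rose in V5 IP and 31 in GFP IP. Beside Elavl2, Celf1, a regulator of splicing and mRNA decay, rose 6.82-fold in V5 IP and 7.50-fold in GFP IP. Cnot3, of the CCR4-NOT deadenylase complex, fell by 1.28 and 1.37 on the log2 scale, and Fxr2, a relative of the fragile X protein, by 0.89 and 0.96. The median lay 1.58 above that of all genes in V5 IP (camera adjusted p = 6.93e-10; 2.03 and 1.19 within slides) and 1.67 above it in GFP IP (1.5e-09; 2.02 and 1.36), or 1.10 with normexp. Against input 26 rose and 1 fell in V5 IP (adjusted p = 4.57e-07; a shift of 1.23, and 1.38 and 1.15 within slides), and 25 rose and 1 fell in GFP IP (4.89e-07; 1.28, and 1.16 and 1.18). The adjusted p was 0.646 with an estimated correlation in all of these.

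Known DAZL targets were higher in both IPs as well. Of 16 measured members 11 rose and 1 fell in each IP against mock IP, and 12 rose when adjusted over the list alone. Some of these genes may have become known through work on these samples, so the list is not independent evidence of its direction. Dazl itself is a member and was among the 11 that rose. Dazl and Nanos3 are also on the primordial germ cell list, Suz12 on the Polycomb list and Sox2 on the pluripotency list. Those lists are therefore not fully separate from this one. Sdad1, a ribosome biogenesis gene, rose 9.20-fold in V5 IP and 8.95-fold in GFP IP, with its other probe moving the opposite way. Suz12, a core Polycomb gene, rose 6.68-fold and 6.21-fold. Nanos3, a germ cell survival gene, fell by 0.85 and 0.84 on the log2 scale. Sycp1, a synaptonemal complex gene, did not pass (adjusted p = 0.218 in V5 IP and 0.140 in GFP IP). The relative median was 2.13 in V5 IP (camera adjusted p = 6.34e-06; 2.50 and 1.74 within slides) and 2.23 in GFP IP (1.12e-05; 2.49 and 1.98). Against input 9 rose in each IP, and 1 fell in V5 IP and 2 in GFP IP (adjusted p = 0.00633 and 0.00814). These shifts were 1.36 in V5 IP (1.58 and 1.32 within slides) and 1.44 in GFP IP (1.62 and 1.47). The adjusted p was 0.646 with an estimated correlation in all 4 comparisons.

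Pluripotency and primordial germ cell genes were also higher than in mock IP. Of 28 pluripotency genes 13 rose and 2 fell in V5 IP, and 13 rose and 4 fell in GFP IP. When adjusted over the list alone, 14 and 13 rose. Klf5, a Krüppel-like transcription factor gene, rose 6.06-fold and 6.54-fold. Mybl2 fell by 1.03 and 1.12 on the log2 scale, and Nr0b1 by 0.70 and 0.95. The pluripotency list was shifted by 1.31 in V5 IP (1.74 and 0.87 within slides) and by 1.27 in GFP IP (1.65 and 0.90; 0.77 with normexp), with a camera adjusted p of 0.00059 and 0.000695. The adjusted p was 0.685 with an estimated correlation in both. Of 28 germ cell genes 10 rose and 3 fell in each IP (16 rose in GFP IP with the slide as a block), and adjusted over the list alone 10 and 14 rose. Kit, the receptor for stem cell factor, rose 9.50-fold and 10.5-fold, and Prdm1, a regulator of germ cell specification, 8.58-fold and 8.75-fold. Ifitm3 fell by 0.96 and 1.17 on the log2 scale. Germ cell genes were shifted by 1.23 in V5 IP (1.55 and 0.80 within slides) and by 1.37 in GFP IP (1.62 and 1.06; 0.82 with normexp), with a camera adjusted p of 0.00109 and 0.00129, and the adjusted p was 0.646 with an estimated correlation. Against input the germ cell list did not pass: 10 rose and 4 fell in V5 IP (adjusted p = 0.339), and 9 rose and 6 fell in GFP IP (0.308). It lay lower in mock IP than in input (0.00462, and an adjusted p of 0.685 with an estimated correlation).

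Polycomb genes were higher in the IPs than in mock IP and input. Against mock IP 13 of 31 rose and 6 fell in V5 IP, and 13 rose and 5 fell in GFP IP, while 14 and 13 rose when adjusted over the list alone. Rnf2, a ubiquitin ligase for histone H2A, rose 8.76-fold and 8.43-fold, and Mtf2, a partner of the histone methyltransferase complex, 6.53-fold and 6.26-fold. Phf1 fell by 1.13 and 1.10 on the log2 scale. Relative medians were 0.92 in V5 IP (1.27 and 0.55 within slides) and 1.09 in GFP IP (1.40 and 0.78; 0.64 with normexp), with a camera adjusted p of 0.00405 for each. Against input 16 rose and 2 fell in each IP (0.00031 for each; 1.42 and 0.93 within slides in V5 IP, 1.59 and 1.06 in GFP IP), and the adjusted p was 0.646 with an estimated correlation in all of these. Genes of DNA and histone methylation did not pass against mock IP (adjusted p = 0.117 in V5 IP and 0.0611 in GFP IP), but did with the slide as a block (0.0496 and 0.0251). Without the block the adjusted p was 0.685 with an estimated correlation in both. Kmt2a, a histone methyltransferase, rose 2.18-fold and 2.30-fold, and Kdm4b, a histone demethylase, fell by 1.19 and 1.29 on the log2 scale. Against input 8 of 34 members (13 with the slide as a block) rose and 3 fell in V5 IP (adjusted p = 0.0212; a shift of 0.55, or 0.84 with normexp, and 0.43 and 0.61 within slides), and 12 rose and 2 fell in GFP IP (0.0147; 0.53 and 0.62). The adjusted p was 0.646 with an estimated correlation in both, and with quantile normalization the V5 call ended.

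mRNAs of oxidative phosphorylation were lower in both IPs than in mock IP. Of 73 measured members 44 fell and 1 rose in V5 IP, and 56 fell and 1 rose in GFP IP, while 54 and 63 fell when adjusted over the list alone. Atp5e, an ATP synthase subunit, fell by 1.42 and 1.81 on the log2 scale. Ndufc2, a complex I subunit, rose 4.74-fold and 5.01-fold. The relative medians were -0.51 in V5 IP (-0.80 and -0.28 within slides) and -0.69 in GFP IP (-1.03 and -0.41; -1.16 with normexp), with a camera adjusted p of 8.85e-06 and 4.89e-07. Against input 30 fell in V5 IP and 40 in GFP IP, and 1 rose in each, with relative medians of -0.65 (9.69e-08; -0.77 and -0.57 within slides) and -0.81 (1.5e-09; -0.99 and -0.73). The V5 shift against input was -0.08 with normexp and -0.98 with quantile normalization. The adjusted p was 0.685 with an estimated correlation in these 4 comparisons.

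Cytosolic ribosomal protein mRNAs fell for 26 of 78 members in V5 IP and for 47 in GFP IP against mock IP, and none rose, while 36 and 50 fell when adjusted over the list alone and 59 and 69 with the slide as a block. Rpl26 fell by 1.07 and 1.32 on the log2 scale. Relative medians were -0.31 in V5 IP (-0.52 and -0.12 within slides) and -0.47 in GFP IP (-0.71 and -0.23), with a camera adjusted p of 9.32e-06 and 6.86e-07. The adjusted p was 0.685 with an estimated correlation in both. With quantile normalization the V5 call ended (0.148) and the shifts were -0.0061 and -0.12, while the GFP shift was -0.98 with normexp. Against input the list did not pass in V5 IP (adjusted p = 0.339), where its median (0.05) and mean (-0.11) differed in sign. In GFP IP it passed against input (0.0458; -0.29 and -0.01 within slides), but not with the slide as a block (0.0882), and the adjusted p was 0.819 with an estimated correlation. The GFP shift against input, -0.10, was 0.07 with normexp and -0.32 with quantile normalization.

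Replication-dependent histone mRNAs fell for 14 of 28 members in V5 IP and for 22 in GFP IP, and 3 rose in each. Adjusted over the list alone, 17 and 23 fell, and 23 fell in each with the slide as a block. H1f4, a linker histone gene, fell by 1.77 and 2.09 on the log2 scale, H1f5 by 1.52 and 2.24, and H3c4 rose 3.05-fold and 3.22-fold. The relative medians were -0.53 in V5 IP (-0.71 and -0.33 within slides) and -0.75 in GFP IP (-1.01 and -0.50). Their camera adjusted p was 0.0147 and 0.00339, with an adjusted p of 0.692 and 0.685 with an estimated correlation. Without V5 2 the V5 call of this list ended. Probes of ribosomal protein and histone genes may also read near-identical copies.

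Markers of other cell types were examined as lists too. Fibroblast and feeder genes fell for 11 of 27 members in V5 IP and for 12 in GFP IP, and 1 rose in each. Acta2, smooth muscle actin, fell by 1.28 and 1.48 on the log2 scale, and Timp3, a metalloproteinase inhibitor gene, rose 6.22-fold and 6.74-fold. Fibroblast genes were shifted by -0.52 in V5 IP (-0.81 and -0.25 within slides) and by -0.65 in GFP IP (-0.95 and -0.34), with a camera adjusted p of 0.0176 and 0.0081 (adjusted p = 0.685 with an estimated correlation). Mesoderm and cardiac genes fell for 9 of 26 members in V5 IP and for 12 in GFP IP, and 1 rose in each. Myl7, an atrial myosin light chain gene, fell by 1.35 and 1.59, Bmp4 fell by 1.09 and 1.31, and Isl1 rose (adjusted p = 0.0103 and 0.00571). Isl1 was well above background on 1 of 2 mock arrays, so no fold is given. Mesoderm genes were shifted by -0.42 in V5 IP (-0.62 and -0.31 within slides) and by -0.56 in GFP IP (-0.64 and -0.37), with a camera adjusted p of 0.0282 and 0.0147 (adjusted p = 0.646 with an estimated correlation). With normexp these shifts were -0.20 and -0.34. The mesoderm call ended with quantile normalization in V5 IP and with normexp in GFP IP. Adjusted over the list alone, 11 and 13 fibroblast genes and 11 and 14 mesoderm genes fell, and with the slide as a block 22 and 22 fibroblast genes and 19 and 18 mesoderm genes. Genes of the protein translocation machinery of the endoplasmic reticulum rose for 10 of 36 members in V5 IP and for 11 in GFP IP, and 3 and 4 fell. Sec62 rose 6.64-fold and 6.48-fold, and Ssr4 fell by 1.19 and 1.39 on the log2 scale. This list was shifted by 0.57 in V5 IP (0.76 and 0.40 within slides) and by 0.61 in GFP IP (0.75 and 0.54), with a camera adjusted p of 0.00737 and 0.00773 (adjusted p = 0.685 with an estimated correlation). The V5 shift was 0.37 with quantile normalization and the GFP shift 0.11 with normexp. Both calls ended without mock 2. Against input the list did not pass: 8 rose and 4 fell in V5 IP (adjusted p = 0.574), where its relative median (-0.04) and mean (0.26) differed in sign, and 7 rose and 4 fell in GFP IP (0.526). It lay lower in mock IP than in input (0.0081, and an adjusted p of 0.685 with an estimated correlation).

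The remaining lists did not pass in either IP against mock IP. The camera adjusted p in V5 IP was 0.301 for meiosis, 0.583 for apoptosis, 0.0752 for mitosis and cell cycle, 0.853 for endoderm, 0.0989 for neuroectoderm and neurons, 0.577 for blood and endothelium, 0.082 for trophoblast (0.0419 with the slide as a block, and an adjusted p of 0.685 with an estimated correlation and no block) and 0.31 for non-coding RNA. In GFP IP these values were 0.528, 0.492, 0.0752, 0.835, 0.0937, 0.702, 0.131 and 0.159. Single members still rose: Elavl4, a neuronal relative of Elavl2, 9.07-fold, Pmaip1, a pro-apoptotic BCL2 family gene, 8.24-fold, Xiap, a caspase inhibitor gene, 6.44-fold, Meioc, a meiosis gene, 4.79-fold, and Rb1, the retinoblastoma gene, 4.45-fold in V5 IP. Ncam1, a neural adhesion gene, rose 4.42-fold, with 2 of its other probes moving the opposite way. Rec8, a meiotic cohesin gene, fell by 1.23 on the log2 scale, Krt8, an epithelial keratin gene, by 1.14, and the non-coding RNA H19 by 1.22.

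**Figure D3:**
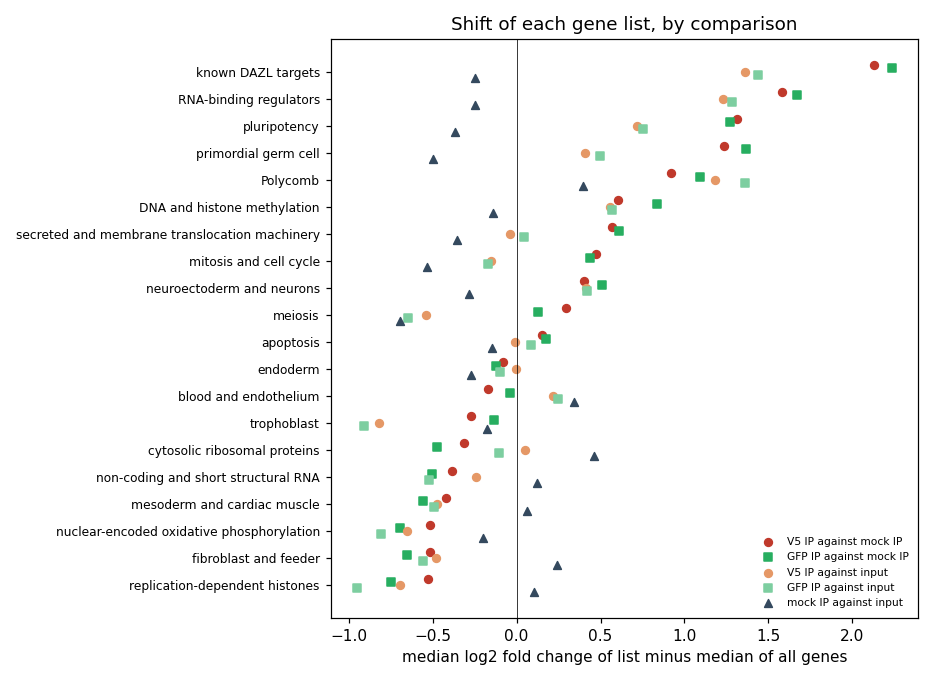
Median log2 fold change of each of 20 gene lists minus the median of all genes, in 5 comparisons; each point is 1 list in 1 comparison. In V5 IP against mock IP the values ran from -0.53 for replication-dependent histones to 2.13 for known DAZL targets.

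V5 IP against input compares the recovered RNA with the RNA of the lysate. Gsx2, a homeobox gene, rose 15.6-fold (log2 3.97 ± 0.27, adjusted p = 0.00207), Aard 15.0-fold and Paqr9 13.9-fold. Foxa1 rose at least 8.25-fold, and the olfactory receptor genes Olfr866 and Olfr18 at least 7.97-fold and at least 5.83-fold. In GFP IP, Olfr866 was well above background on 0 of 2 arrays and Olfr18 on 1 of 2, while Foxa1 was on 2 of 2. The zinc finger genes Zfp946, Zfp758, Zfp987, Zfp985 and Zfp936 and the kinetochore gene Ndc80 were lowest. Zfp987 lay at -4.85 ± 1.08 (adjusted p = 0.0162) and Zfp985 at -4.71 ± 1.12 (adjusted p = 0.0205). The other 4 were well above background on 1 of 2 V5 arrays, so no fold is given for them. Probes of the olfactory receptor and zinc finger families may also read near-identical copies.

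By limma, 2687 genes were higher and 2599 lower in V5 IP than in input, and with the slide as a block 3881 were higher and 4600 lower. Within slides, 3524 genes were at least 2-fold higher and 3513 at least 2-fold lower on slide 1, and 2417 and 2338 on slide 2. With normexp 1185 were higher and 331 lower. The higher and lower counts became 904 and 293 without input 1, 1015 and 414 without input 2, and 1215 and 566 without V5 1. Without any of these 3 arrays in turn, Olfr18 and all of the lowest genes except Zfp936 lost their call, with an adjusted p of up to 0.161 for Olfr18 and 0.144 for Zfp758. With normexp Olfr18 changed sign, and Olfr866, Foxa1 and Zfp936 lost their call.

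GFP IP against input gave many of these genes again. Gsx2 rose by 4.00 ± 0.27 on the log2 scale (adjusted p = 0.0018), Paqr9 14.7-fold and Eif1b, a translation initiation factor gene, 13.8-fold. Foxa1 rose at least 8.44-fold, the lipocalin gene Lcn5 at least 6.19-fold and Tmem132cos at least 4.21-fold. Lcn5 and Tmem132cos were each well above background on 1 of 2 V5 arrays. Zfp946, Zfp758, Zfp987, Zfp985, Ndc80 and Eif5b were lowest, and Zfp946, Zfp758 and Ndc80 were well above background on 1 of 2 GFP arrays, so no fold is given for them. Zfp987 lay at -5.62 ± 1.08 (adjusted p = 0.00828) and Eif5b, an initiation factor of ribosome joining, at -4.84 ± 0.65 (adjusted p = 0.00268).

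By limma, 3047 genes were higher and 3203 lower in GFP IP than in input, and with the slide as a block 4180 were higher and 5099 lower. Within slides, 3606 genes were at least 2-fold higher and 3852 at least 2-fold lower on slide 1, and 2783 and 2750 on slide 2. With normexp 1250 were higher and 475 lower. The higher and lower counts became 1223 and 596 without input 1, 1319 and 734 without input 2, and 1479 and 861 without GFP 1. Of the lowest genes Eif5b kept its call whichever array was left out. Each of the other 5 lost it without input 1, input 2 or GFP 1, but not all of them in each case. Tmem132cos lost its call without input 1 (0.0506), and with normexp it, Lcn5 and Foxa1 lost theirs.

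Further lists passed against input. Replication-dependent histones were lower in V5 IP (5 of 28 fell and 3 rose, adjusted p = 0.0336; -0.65 and -0.71 within slides) and in GFP IP (14 fell and 4 rose, 0.00577; -0.86 and -0.90), and the adjusted p was 0.721 and 0.685 with an estimated correlation. With the slide as a block 14 and 22 histone genes fell. Without V5 2 or input 2 the histone call in V5 IP ended. Trophoblast genes were lower, with 7 of 15 down and 1 up in V5 IP (0.026; -0.96 and -0.68 within slides) and 6 down and 1 up in GFP IP (0.0458; -1.05 and -0.80), and the adjusted p was 0.685 with an estimated correlation. Pluripotency genes were higher, with 11 of 28 up and 2 down in V5 IP (0.0384; 0.91 and 0.51 within slides) and 10 up and 3 down in GFP IP (0.033; 0.75 and 0.62), and the adjusted p was 0.721 with an estimated correlation. In GFP IP fibroblast genes (9 of 27 down and 2 up, 0.0413; -0.71 and -0.51 within slides) and mesoderm genes (8 of 26 down and 1 up, 0.0458; -0.68 and -0.36) were lower, with an adjusted p of 0.685 and 0.679 with an estimated correlation. With normexp the shifts were -0.16 for histones in V5 IP (-0.69 as reported), -0.33 and -0.58 for trophoblast genes in V5 IP and GFP IP (-0.82 and -0.91), and -0.24 and -0.15 for fibroblast and mesoderm genes in GFP IP (-0.56 and -0.49). The pluripotency shift in V5 IP, 0.72, was 1.25 with normexp and 0.46 with quantile normalization. In V5 IP the fibroblast and mesoderm lists did not pass (adjusted p = 0.082 and 0.0885), and the difference between the IPs was not tested for lists. The trophoblast and pluripotency calls ended without input 2, and those of V5 IP without V5 1 and of GFP IP without GFP 1. Without mock 1 or mock 2 the pluripotency calls and the trophoblast call of GFP IP ended, and the fibroblast and mesoderm calls without input 1.

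Mock IP against input shows which RNAs gave more or less signal, relative to their array, with IgG than in the lysate. Dbn1, an actin-binding protein gene, rose 28.9-fold (log2 4.85 ± 0.24, adjusted p = 0.00143). The non-muscle myosin genes Myh14 and Myh10 rose 17.4-fold and 12.7-fold, and Rmrp, the RNA of RNase MRP, rose 17.7-fold. Cacng3 and Fam71b rose at least 6.24-fold and at least 5.42-fold. The antisense RNA Kcnq1ot1 (adjusted p = 0.0499), the meiosis gene Hormad1 (adjusted p = 0.0391), Ndc80, the spindle checkpoint kinase gene Ttk and Runx1t1 were among the lowest, each well above background on 1 of 2 mock arrays, so no fold is given. Ankrd34b was at least 3.42-fold lower. Primordial germ cell, meiosis, mitosis and translocation genes were lower as lists, with relative medians of -0.50, -0.69, -0.53 and -0.35 (camera adjusted p = 0.00462, 0.00129, 0.0013 and 0.0081). Of their members 4 of 28, 5 of 23, 6 of 50 and 4 of 36 fell, and 1, 0, 2 and 0 rose. Within slides the shifts were -0.53 and -0.44, -0.76 and -0.55, -0.61 and -0.48, and -0.38 and -0.37. Ribosomal protein genes were higher as a list (0.46, adjusted p = 9.32e-06; 0.63 and 0.32 within slides), although none of 78 rose singly without the slide as a block, and 34 rose with it. With the block 8 primordial germ cell, 17 mitosis and 9 translocation genes fell. With quantile normalization the ribosomal shift was -0.10 and its call ended (0.742). With normexp the ribosomal shift was 0.99, and those of the germ cell, meiosis, mitosis and translocation lists were -0.16, -0.30, -0.21 and 0.13. With an estimated correlation the adjusted p was 0.646 for meiosis and 0.685 for the other 4 lists.

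By limma, 1262 genes were higher and 767 lower in mock IP than in input, and with the slide as a block 4068 were higher and 2539 lower. Within slides, 3690 genes were at least 2-fold higher and 2422 at least 2-fold lower on slide 1, and 1406 and 1282 on slide 2. With normexp 8 were higher and 0 lower, and with centring on the median of the tested genes 804 were higher and 840 lower. The total of 2029 became 0 without mock 1, 1 without input 1, 7 without input 2, 1226 without GFP 1 or GFP 2, and 3879 without mock 2. All 12 named genes lost their call without mock 1, where the adjusted p of Dbn1 was 0.0534.

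V5 IP and GFP IP did not differ in any gene by limma, and 187 of 19032 genes had an unadjusted p under 0.05. Dazl differed by -0.08 ± 0.39. The 95% interval of the difference lay within 2-fold either way for 12827 genes (67.4%), and its median half-width was 0.71. These intervals took no account of the slides, though the deviations of same-numbered V5 and GFP arrays correlated at 0.78. With the slide as a block, 403 genes had an unadjusted p under 0.05. Toward V5 IP the smallest p-values belonged to Cbln3, Nav1, Glra4, Ttc24, Olfr866 and Cldn13, and Nav1 had 1.59 ± 0.25 (adjusted p = 0.471). Toward GFP IP they belonged to Podn, Astn2, Muc2, Clip3, Ackr4 and Spag6, and Muc2 had -1.69 ± 0.27 (adjusted p = 0.471). With the slide as a block 1 gene passed, and 9 passed without V5 1, 6 without V5 2 and 2 without GFP 2.

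The fold changes of both IPs over mock IP followed each other, with r = 0.963 across genes, which are not independent replicates. Simulated unchanged IPs that shared the mock arrays gave r = 0.50 with independent arrays, and r = 0.77 with same-numbered arrays correlated as measured, a simulation chosen after seeing the data. The covariance was 1.03. The simulated covariance was 0.07 with independent arrays (a difference of 0.96) and 0.05 with correlated arrays (a difference of 0.98). Fold changes that shared no array or slide, V5 on slide 1 with GFP on slide 2 and the reverse, correlated at 0.861 and 0.857, and those within slides at 0.955 and 0.926. Genes higher in both IPs than in mock IP numbered 2704, where independent lists would share 452 and the simulations gave 0.01 with independent arrays and 0 with correlated arrays. No gene was changed in any simulated group, so hardly any could be called and these simulated counts had to lie near 0. They hold no mock IP that differs from the other groups, so they cannot exclude an overlap that comes from the mock arrays. Genes lower in both numbered 3811, where independent lists would share 1077. The 3811 became 48 without V5 1, 73 without mock 1, 113 without GFP 1, 403 without input 1 or without input 2, 1832 without V5 2, 1911 without GFP 2 and 9 with normexp. Part of the excess may come from the shared mock arrays, which cannot be split with 2 arrays, and from the shared slides. The 2704 became 1044 without V5 1, 1055 without mock 1, 1319 without GFP 1, and 1767 without input 1 or without input 2.

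Genes higher in both IPs than in both controls numbered 1903, of which 567 were shared by all settings that kept the 8 arrays and 350 by all 20 settings. The 1903 became 710 without V5 1, 739 without input 1, 799 without input 2, 905 without GFP 1 and 996 without mock 1. In the mean of both IPs against mock IP, Elavl2 rose by 3.92 ± 0.25 on the log2 scale (adjusted p = 0.000716), followed by Nmt2, Taf7 and Cyp51, with Synpr at least 7.88-fold and Foxa1 at least 4.88-fold higher. Elavl2 and Cyp51 were among the genes higher than both controls in all 20 settings, while Nmt2, Taf7, Synpr and Foxa1 were not. Cacng3 was at least 4.87-fold and Cypt2 at least 2.82-fold lower, and Qrich2 lay at -3.36 ± 1.08 (adjusted p = 0.0352). The chemokine receptor gene Ccr10, Il1f10 and Fam71b were lower as well (adjusted p = 0.0356, 0.0238 and 0.0278), but each was well above background on 1 of 4 IP arrays, so no fold is given. Of the 6 lowest, Cacng3 kept its call whichever array was left out, and all 6 lost it with normexp. By limma, 3384 genes were higher and 6084 lower, and without mock 1 these counts became 1969 and 1523. The higher and lower counts were 1883 and 1815 with normexp, 3810 and 3846 with the authors' deposited table, and 3667 and 4039 with centring on the median of the tested genes.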

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

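Both tests of the excess of lower calls given here were chosen only after the result was seen. Synthetic spike-in RNA, which the comparisons did not use, read higher relative to the rest of the array in mock IP than in input. The log2 signal of 6 spike-in probes minus the array's 75th percentile was 5.04 on mock 1 and 2.39 on mock 2, against 1.19 and 0.73 on the input arrays. It was 1.92 and 0.36 on the V5 arrays and 2.06 and 0.57 on the GFP arrays. How the spike-in was added is not given in the sources used here. Amounts of RNA were therefore not compared, and higher and lower refer to signal relative to each array.

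More genes were called lower than higher in the IPs against mock IP. Of the calls in V5 IP 59.4% were lower. There the higher calls outnumbered the lower with no filter on dim probes (1946 and 978) and with only the groups compared (2037 and 382). The same held with a 2-fold minimum (2534 and 2417), but not with quantile normalization (2954 and 3964) or the slide as a block (3693 and 7311). With arrays centred on the median of the tested genes, 35.5% of the genes called in V5 IP against mock IP were lower. Such centring moves all genes of an array alike, so this share does not decide whether scaling is the cause. The median log2 fold change of all genes was -0.44 as reported and -0.29 with that centring. Of the genes at least 2-fold apart, 61.0% were lower in V5 IP on slide 1 and 23.1% on slide 2, so little RNA on mock 1 may account for it, though V5 1 lies on the same slide. The 4066 lower calls in V5 IP became 77 without mock 1, 5095 without mock 2, 55 without V5 1 and 426 without either input array in turn. These explanations were not separated from each other. A biological excess of RNAs left out of the IPs was not tested.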

How the results depend on the processing

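Centring on the median of the tested genes, and list tests without single arrays, were chosen only after the results were seen. Normexp gave 958 genes for V5 IP against mock IP, 1623 for GFP IP against mock IP, 1516 for V5 IP against input, 1725 for GFP IP against input, 8 for mock IP against input, 3698 for the mean of both IPs, 941 higher and 9 lower in both IPs than in mock IP and 718 higher than in both controls. It gave a correlation of the IPs of 0.914 and kept 102 of 225 named calls. With normexp Cbln3 in GFP IP against mock IP lost its call and changed sign (0.079, limma adjusted p = 0.986). So did Olfr18 in V5 IP against input (-0.15, adjusted p = 0.903) and Sox7 in V5 IP against mock IP (-0.12, adjusted p = 0.905). Hbb-bh1 in GFP IP against mock IP did as well (0.26, adjusted p = 0.963). The ribosomal list in V5 IP against input and the oxidative phosphorylation list in mock IP against input did not pass as reported (camera adjusted p = 0.339 and 0.420). With normexp both passed upward (0.0466 for each), where the direction as reported was downward. With no filter on dim probes the counts were 2924 for V5 IP against mock IP, 140 for mock IP against input and 917 lower in both IPs than in mock IP, and the correlation was 0.907. With the replicate block they were 11004 for V5 IP against mock IP, 8481 for V5 IP against input, 6607 for mock IP against input, 6725 lower in both IPs than in mock IP and 1 for V5 IP against GFP IP. With only the groups compared they were 2419 for V5 IP against mock IP, 43 for mock IP against input and 347 lower in both IPs than in mock IP. A further 2-fold minimum left 5985 for the mean of both IPs and 2225 lower in both IPs than in mock IP, by its construction. The authors' deposited table gave 4560, and centring on the median of the tested genes, chosen after seeing the data, 4390 for V5 IP against mock IP, with 1417 and 1460 lower in both IPs than in mock IP. With an estimated correlation 0 gene lists passed. Of the 46 list calls, quantile normalization kept 37 and ended 9, normexp kept 39 and ended 7, and fry kept 30 and ended 16. Not all of the ended list calls are named here. Apart from the 2-fold minimum, the cause was not tested. The block changed no other call of a named gene or list whose values the report gives.

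Leaving out each array in turn gave 1118 to 7845 genes for V5 IP against mock IP, 1476 to 8375 for GFP IP against mock IP, 1197 to 5904 for V5 IP against input, 1819 to 6971 for GFP IP against input, 0 to 3879 for mock IP against input, 0 to 9 for V5 IP against GFP IP and 3492 to 9280 for the mean of both IPs. It gave 1044 to 2677 genes higher and 48 to 4789 lower in both IPs than in mock IP, 710 to 1913 higher than in both controls, a correlation of 0.895 to 0.972, 129 to 205 named calls and 42 to 49 gene lists. For genes not well above background in a group, the signal limits the fold to a bound.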

Other observations

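The list tests of cytoskeleton and Zfp genes given here were chosen only after the leading genes were seen. The 3 tests of their causes were written before their values were seen, except for 1 reading named with it.

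mRNAs of actin and myosin cytoskeleton proteins were higher in mock IP than in input. The list of these genes was written after Dbn1, Myh14 and Myh10 were seen among the highest. Of its 66 measured members 24 rose and 1 fell in mock IP against input, and in V5 IP against mock IP 31 fell and 7 rose. Of the 66, 10 had been seen before the list was written, and 9 of these were among the 24. Gsn, the actin-severing protein gelsolin, lay 2.78 above input in mock IP (adjusted p = 0.00836), and Myo18a, an unconventional myosin gene, 2.75 (adjusted p = 0.00792), both named after their values were seen. Of the 56 members not seen before 15 rose and 1 fell in mock IP against input, where they passed as a list (camera adjusted p = 0.00467), but not with an estimated correlation (adjusted p = 0.831). They did not pass in V5 IP against mock IP (adjusted p = 0.176).

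If little RNA on mock 1 were the cause, the 56 members would lie at or below all genes on slide 2. Their median there was 0.51 above that of all genes, with 42 of 56 above it, so they lay higher on slide 2 as well. The 95% interval, 0.23 to 0.87, came from resampling the members on mock 2 and input 2 alone. It holds no spread between arrays and takes genes as independent, so it cannot decide whether mock 1 was the whole cause. On slide 1, which holds mock 1, the median of the 56 members was 0.15 above that of all genes. The shift was thus not larger on the slide of mock 1, but each slide has only 1 mock array and 1 input array. The prediction against mock 1 had asked for a median over 0.5, and reading an interval above 0 as enough was decided after the value was seen. RNA that stays on the beads without the tagged protein may be a cause, and would put the same genes above input in V5 IP. The 56 members had a median of 0.30 above that of all genes there, with an interval over members of -0.08 to 0.66. Of the 10 members seen before, 9 rose and 0 fell in V5 IP against input (relative median 2.30) and in GFP IP (2.05). These 10 had been seen before the list was written, and the comparisons share the input arrays, so they do not settle it. RNA staying on the beads thus stays open, as does a low RNA amount on mock 2.

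Of the 6 lowest genes named in V5 IP against input 5 were zinc finger (Zfp) genes, but the wider group did not pass. Of 316 measured Zfp genes 48 were higher and 58 lower in V5 IP than in input, and 55 and 77 in GFP IP. Without the named genes and Zfp820, which was left out because it had been seen among the lowest in a first look, the other 310 did not pass as a list (camera adjusted p = 0.452 in V5 IP and 0.377 in GFP IP). They passed in mock IP against input (0.00458, a relative median of -0.51), but not with an estimated correlation (adjusted p = 0.831).

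If the 5 low Zfp genes came from slide 1 alone, other Zfp genes would not be lower on slide 2. The 310 had a relative median of -0.026 on slide 2 in V5 IP against input (95% interval over members -0.18 to 0.11). This cannot decide it, because the 310 did not pass as a list over both slides either. The 5 Zfp genes named in V5 IP against input lay between -3.55 and -3.30 on slide 2, where all 5 were well above background on the V5 array. These 5 were thus low on slide 2 too, though the naming rule asked for both V5 arrays below both input arrays. Signal shared between near-identical family members was not tested.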
